A study of Rattus norvegicus with 19 samples.

How the data were processed

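RNA from the left ventricle of 19 male Dahl salt-sensitive rats, a strain whose blood pressure rises on a salty diet, was measured on 1 Affymetrix expression array per rat. The labels give total RNA with an integrity number above 9 and biotin-labelled cRNA made from 5 ug. All rats ate 6% NaCl from 6 weeks of age. The baseline group was taken after 5 weeks of that diet, and the other 4 groups after 4 more weeks, during which they received vehicle, paricalcitol (an activator of the vitamin D receptor, 200 ng per injection, 3 injections a week), enalapril (an inhibitor of angiotensin-converting enzyme, 90 ug a day) or both drugs. Groups held 4 arrays each, except 3 for enalapril. The numbers in the sample descriptions form a separate block for each group, so cohort and group cannot be told apart.

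The deposited values are linear intensities, 1 per probe set and array, and the tools with which the authors made them are not given in the sources used here. Between 16% and 18.2% of the values on an array were below 0, so a background had been subtracted. Array medians ran from 43.6 to 72.6, and the median log2 ratio of an array to the median array from -0.30 to 0.31. The number of arrays limits the precision.

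Because of these offsets the arrays were quantile normalized together, values below 0 were set to 0, and log2 of the value plus 16 was taken. That choice was made from the offsets, before any test was run; the plan had named the deposited values without equalisation between arrays, which were run as an alternative. Quantile normalization nearly fixes the few brightest transcripts. Of the 31099 probe sets, 20826 named 1 gene, and each of 14217 genes was represented by its probe set with the highest mean over all arrays. Probe sets that named several genes (436) or none (9780), with 57 control probe sets, were left out of the comparisons.

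A group-means model over all 19 arrays was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend on mean level. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. The 10 comparisons were vehicle against baseline, each drug group against vehicle and against baseline, the combination against each drug, and the interaction of both drugs. Differences are log2, the group named first minus the second, with limma's standard error (SE). Gene groups (38 lists: 26 of pathways and processes, 12 of cell markers, 626 measured members) were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data, with fry and with exact permutation tests of list scores per array. The groups, comparisons, gene lists, thresholds and most alternatives were fixed before the data were examined. Genes were named by a rule: those past the threshold without overlap between groups (up to 8 per direction with the largest change), the 3 with the smallest p where fewer passed, up to 4 members of each list past the threshold in camera and of the renin-angiotensin and vitamin D lists, and a fixed panel of cardiac genes; exceptions are stated.

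The procedure was tested on simulated data made from these arrays. With 100 genes shifted by 1 log2 unit in vehicle against baseline, 81.6% were found, and 43.6% of those shifted by 0.5, with 6.4% of the calls false. The shifted genes were drawn from the brighter ones, and the noise was drawn independently for each gene. These percentages therefore do not cover faint genes, or genes that vary together as on the real arrays. With no shift, camera at the preset correlation still called at least 1 list in 19 of 20 runs (mean 6.85 of 38 lists), against 0 of 20 runs with an estimated correlation. Calls at the preset correlation are therefore given with the estimated version beside them. With an estimated correlation and 3 lists shifted by -0.40, 75% of the shifted lists were found.

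The arrays carry replicate numbers 1 to 4 in every group but enalapril, which has 1 to 3. Correlations of deviations from group means between arrays of equal number were all above 0.1 in 1 of 10 pairs of groups, paricalcitol and the combination (0.28 to 0.50), and a fit with the replicate number as a block was run as an alternative. The labels used here do not pair rats by that number. The other alternatives were each array centred on its median, cyclic loess, dimmer genes left out, no variance trend, array weights, only the groups compared, probe sets averaged or tested singly, other pseudocounts, the red cell marker score as a covariate, and each array left out in turn. Dimmer genes were those with a mean log2 value at or below the median of all genes.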

Results

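Expression of 14217 genes was measured in the left ventricle of 19 Dahl salt-sensitive rats: 4 at baseline (5 weeks of high salt), and, 4 weeks later, 4 given vehicle, 4 paricalcitol, 3 enalapril and 4 enalapril plus paricalcitol, here called the combination. The depth of an array has no count, and array medians lay between 43.6 and 72.6 intensity units before normalization. The first principal component, over 8710 brighter genes, held 24.7% of the variance and separated arrays within both groups given paricalcitol more than it separated groups. Red cell markers also varied: their score per array had a mean of -0.16 ± 0.84 (SD, n = 4) in the paricalcitol group and -0.19 ± 0.89 (SD, n = 4) in the combination, against 0.02 ± 0.39 (SD, n = 4) in vehicle and 0.31 ± 0.38 (SD, n = 4) at baseline. In enalapril it was 0.03 ± 0.66 (SD, n = 3), so such variation was not limited to paricalcitol.

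**Figure D1:**
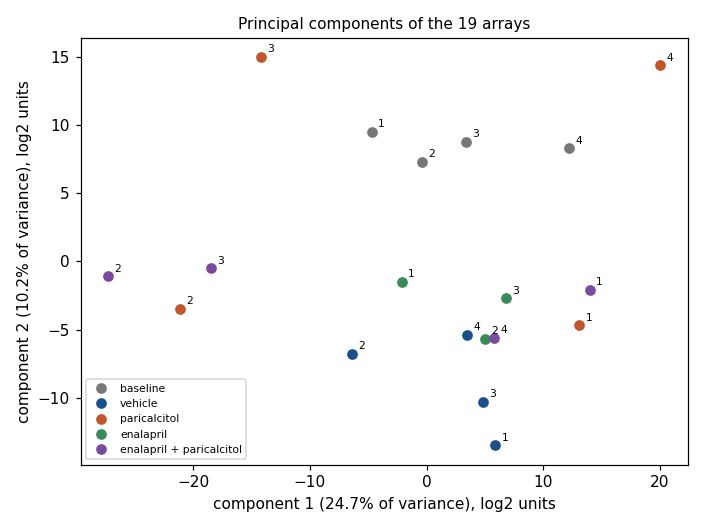
Each point is 1 array, placed by its scores on the first and the second principal component of log2 intensities (log2 units) and coloured by group, with its replicate number beside it. The paricalcitol arrays spread from -21.1 to 20 on the first component, and the vehicle arrays from -6.4 to 5.9.

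Vehicle against baseline asked what 4 more weeks of high salt, with 4 more weeks of age and with vehicle injections, did to the heart. These cannot be told apart from a difference between the cohorts. Igf2, an insulin-like growth factor, fell by a log2 difference of -0.91 (SE 0.14, n = 4 and 4), Cd93, a surface protein of endothelial cells, of -1.13 (SE 0.18), and Podxl, a sialomucin of the vessel lining, of -0.54 (SE 0.08). The size of the Igf2 fall depended on the processing: it ran from -1.13 to -0.109 over the alternatives and omissions (highest limma adjusted p = 0.708). Lss, lanosterol synthase, rose by 0.90 (SE 0.15), and Insig1, a regulator of sterol synthesis, by 0.51 (SE 0.08). On the single arrays Lss was 5.74 to 5.92 at baseline and 6.61 to 6.85 in vehicle. It was 5.85 to 5.97 with paricalcitol, 5.93 to 6.15 with enalapril and 6.08 to 7.04 in the combination. Insig1 was 8.64 to 8.97 at baseline, 9.21 to 9.34 in vehicle and 8.88 to 8.98 with enalapril. With paricalcitol it was 8.79 to 9.22, and in the combination 8.84 to 9.01. An offset of the vehicle cohort would also give such rises. Myo5b, an unconventional myosin, also rose, from near the floor of 4 (mean 4.81 ± 0.53, SD, n = 4) to 6.20 ± 0.35 (SD, n = 4), a level at which the difference depends on the processing (0.667 to 2.534 over the alternatives and omissions). The transcriptional regulator Elk3 changed by -0.59 (SE 0.10), Xpo1, a nuclear export receptor, by -0.85 (SE 0.15) and Dtx4, a ubiquitin ligase, by -1.25 (SE 0.22). Nmu, neuromedin U, had a mean of 5.19 ± 0.28 (SD, n = 4) at baseline and lay at or within 0.01 of the floor of 4 on all vehicle arrays. Far1 had 5.31 ± 0.64 (SD, n = 4) at baseline and lay at the floor on all vehicle arrays. No fold is given for these. In all, 12 of 14217 genes passed in limma (3 higher, 9 lower), with adjusted p from 0.0235. That balance depended on the normalization, with 14 higher and 8 lower after median centring, and 0 higher and 3 lower in the deposited values. In this comparison 1308 genes had an unadjusted p under 0.05, where chance gives 711. The groups did not overlap in 7.8% of genes, where chance gives 2.9%.

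Collagen and matrix genes were lower in vehicle than at baseline in 29 of 37 members (median -0.43): Col4a1 had -0.75 (SE 0.18), Col18a1 -0.64 (SE 0.16), Sparc -0.32 (SE 0.08) and Col1a1 -0.92 (SE 0.37). No member passed over all genes, and 5 passed adjusted over the list alone. Camera gave an adjusted p = 5.23e-06 at the preset correlation and an adjusted p = 0.732 with an estimated correlation. Cell cycle genes were lower in 21 of 24 members (median -0.35; 0 passed adjusted over the list alone), with Mcm4 at -0.49 (SE 0.16), at camera adjusted p = 6.02e-05 and adjusted p = 0.732 with an estimated correlation. Cardiac ion channel genes were higher in 14 of 17 members (median 0.27; 0 passed adjusted over the list alone), with Kcnq1 at 0.45 (SE 0.20) and Scn4b at 1.00 (SE 0.41), at adjusted p = 0.0258 and adjusted p = 0.433 with an estimated correlation. Gja1, the main gap junction gene, went the other way at -0.16 (SE 0.06). Markers of smooth muscle cells and pericytes were lower in 9 of 12 members (median -0.19), with Rgs5 at -0.64 (SE 0.16) and Kcnj8 at -0.47 (SE 0.10). Of these 2 passed adjusted over the list alone, and camera gave adjusted p = 0.0292 and adjusted p = 0.732 with an estimated correlation. Single omissions ended the calls of these markers (up to 0.167) and of ion channel genes (0.0987). The fetal and hypertrophy-associated genes had a median of -0.02, Nppb, a natriuretic peptide, 0.37 (SE 0.22), and Myh6, the fast myosin heavy chain, -0.76 (SE 0.48); none passed. Nppa, Myh7, Acta1 and Atp2a2 ranked among the 28 brightest probe sets on every array, where the normalization leaves little room for a difference. Each of the 8 single-array omissions lowered the gene count, to 0 without baseline replicate 1, vehicle replicate 1 or vehicle replicate 4 and at most to 5, without vehicle replicate 2. Nmu and Podxl kept their calls in 3 of the 8, Far1, Igf2, Myo5b and Xpo1 in 1, and the other named genes in 0.

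**Figure D2:**
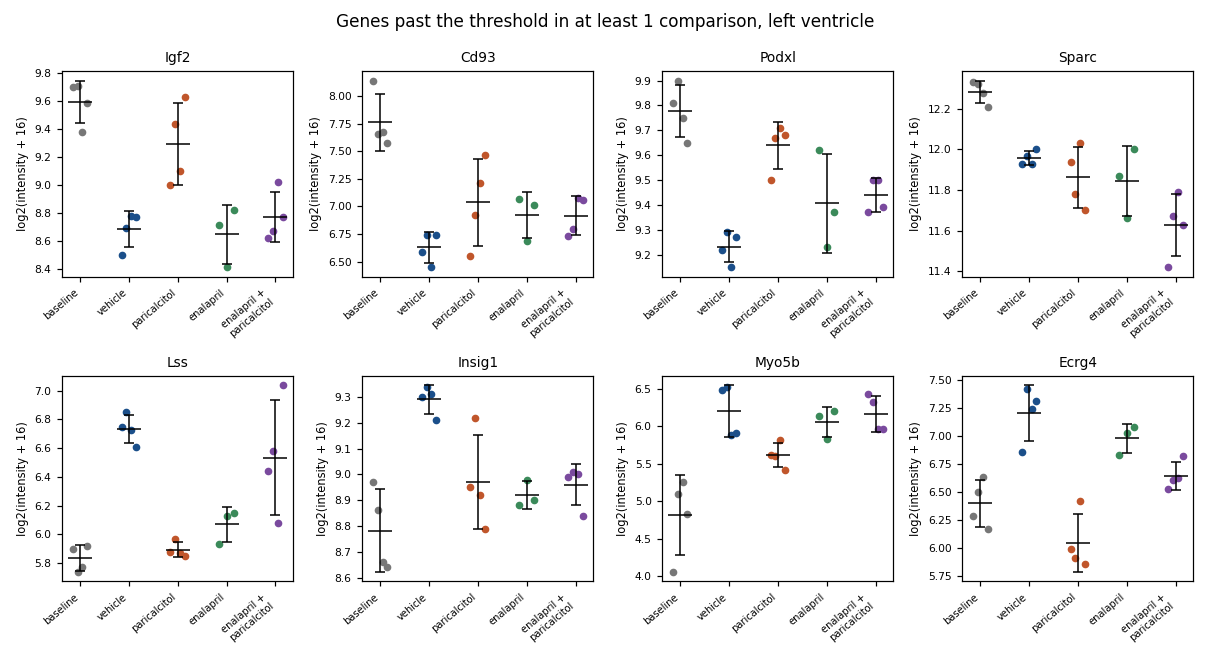
Log2 intensity (value plus 16) of 8 genes past the threshold in at least 1 comparison, with each array as a point, the group mean as a bar and the SD as whiskers. Sparc lay between 11.42 and 11.79 on the 4 combination arrays and between 12.21 and 12.33 on the 4 baseline arrays.

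Paricalcitol against vehicle asked what activation of the vitamin D receptor changed. Ecrg4, which encodes the secreted peptide augurin, fell by 1.16 (SE 0.15, n = 4 and 4; adjusted p = 0.0139), and Atp6v1d, a subunit of the vesicular proton pump, fell by 0.28 (SE 0.04; adjusted p = 0.0358). Among the genes nearest to the threshold, none of which passed, another proton pump subunit, Atp6v0e2, had -0.71 (SE 0.11), and Kcnj8, a potassium channel gene of pericytes, had 0.56 (SE 0.10), each with adjusted p = 0.0606. Vitamin D genes did not pass as a group (18 members, median 0.05, camera adjusted p = 0.521 and adjusted p = 0.845 with an estimated correlation; 0 passed adjusted over the list alone), with a list score of 0.09 ± 0.08 (SD, n = 4) against -0.03 ± 0.07 (SD, n = 4). Of its members, Vdr, the receptor, had -0.03 (SE 0.21), Cdkn1a 0.33 (SE 0.16) and Igfbp3 0.68 (SE 0.34). Of the renin-angiotensin genes (15 members, median 0.01; camera adjusted p = 0.655 and adjusted p = 0.845 with an estimated correlation), Mme, neprilysin, lay near the floor of 4 (4.62 ± 0.29, SD, n = 4, and 4.17 ± 0.26, SD, n = 4, in vehicle), and Ace had -0.42 (SE 0.29). Cyp24a1 was not analysed here.

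Smooth muscle and pericyte markers were higher in the paricalcitol group in 10 of 12 members (median 0.26): Tagln had 0.59 (SE 0.24), Acta2 0.54 (SE 0.22) and Pdgfrb 0.43 (SE 0.15). Camera gave adjusted p = 0.0113 and adjusted p = 0.845 with an estimated correlation, and 1 member passed adjusted over the list alone. Endothelial markers were also higher, in 11 of 12 members (median 0.10), and did not pass (adjusted p = 0.097, and adjusted p = 0.845 with an estimated correlation). Inflammation genes were higher in 27 of 30 members (median 0.21; 0 passed adjusted over the list alone), with the adhesion molecules Vcam1 at 0.62 (SE 0.20) and Selp at 0.57 (SE 0.26), at adjusted p = 0.0342 and adjusted p = 0.845 with an estimated correlation. The inflammation score was 0.78 on paricalcitol replicate 4, whose red cell score was also the highest of the group at 0.70. Without that array the list had adjusted p = 0.493, and without paricalcitol replicate 2 the muscle markers had 0.0968. In all, 2 genes passed in limma, both lower (1 in the deposited values, which was higher), and 1371 had an unadjusted p under 0.05, where chance gives 711. Groups did not overlap in 5% of genes, where chance gives 2.9%. The count rose to 10 without paricalcitol replicate 1 and to 4 without vehicle replicate 1, was 1 without paricalcitol replicate 3, and was 0 without vehicle replicate 3, vehicle replicate 4 or paricalcitol replicate 4.

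Enalapril against vehicle asked what a dose chosen to leave blood pressure unchanged did. No gene passed in limma (smallest adjusted p = 0.435). At an unadjusted p under 0.05 there were 802, where chance gives 711. Markers of T cells were higher in 10 of 11 members (median 0.35), with Cd5 at 0.41 (SE 0.17, n = 3 and 4) and Cd2 at 0.64 (SE 0.33), at camera adjusted p = 0.00804 and adjusted p = 0.462 with an estimated correlation. Macrophage markers were higher in 14 of 15 members (median 0.27), with Csf1r, the receptor of a macrophage growth factor, at 0.35 (SE 0.19), at adjusted p = 0.011 and adjusted p = 0.981 with an estimated correlation. Inflammation genes were higher in 25 of 30 members (median 0.29; adjusted p = 0.0482 and adjusted p = 0.981 with an estimated correlation), with Vcam1 at 0.43 (SE 0.21) and Tnf, listed at 0 on 2 of 3 enalapril arrays, among the 5 that were lower. Genes of muscle atrophy and autophagy were lower in 16 of 18 members (median -0.18), with Trim54 at -0.25 (SE 0.10) and Atg12 at -0.21 (SE 0.07), at adjusted p = 0.00567 and adjusted p = 0.828 with an estimated correlation.

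Immediate early genes, which respond within minutes to a stimulus, were higher in enalapril than in vehicle in 18 of 20 members (median 0.28), with Egr1 at 1.09 (SE 0.70), at adjusted p = 0.0482 and adjusted p = 0.981 with an estimated correlation. Their direction turned without enalapril replicate 2. In these 5 lists 0 members passed adjusted over the list alone. Single omissions ended each call, up to adjusted p = 0.373 for macrophage markers without enalapril replicate 3, 0.0873 for T cell markers and for atrophy genes without enalapril replicate 2, and 0.125 for inflammation genes without vehicle replicate 1. Ace had -0.19 (SE 0.31), Agtr1a, the angiotensin receptor, 0.04 (SE 0.24) and Nppb 0.10 (SE 0.24). The renin-angiotensin list had a median of 0.03 (camera adjusted p = 0.929 and adjusted p = 0.981 with an estimated correlation) and the vitamin D list of 0.02 (the same adjusted p values in both tests). Groups did not overlap in 8.5% of genes, where chance gives 5.7%. In omissions of an array, 1 gene passed without enalapril replicate 1 and 2 without enalapril replicate 2.

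The combination against vehicle asked what both drugs did together. Lsm5, part of an RNA-binding ring that acts in splicing and RNA decay, rose by 0.47 (SE 0.07, n = 4 and 4; adjusted p = 0.0415) and was the 1 gene that passed in limma, with 1092 at an unadjusted p under 0.05 (chance gives 711). Myh6, the fast myosin heavy chain of the adult rat heart, had 1.66 (SE 0.48) without overlap between the groups, and did not pass (adjusted p = 0.451). Fatty acid oxidation genes were higher in 26 of 30 members (median 0.12), with Acaa2 at 0.37 (SE 0.17) and Acadvl at 0.31 (SE 0.14), at camera adjusted p = 0.039 and adjusted p = 0.993 with an estimated correlation. Immediate early genes were lower in 18 of 20 members (median -0.29), with Fos at -1.01 (SE 0.71) and Junb at -0.43 (SE 0.29). Atrophy and autophagy genes were lower in 15 of 18 (median -0.09), with Trim54 at -0.21 (SE 0.09). These lists had adjusted p = 0.039 and 0.0409, and both had adjusted p = 0.993 with an estimated correlation. In these 3 lists 0 members passed adjusted over the list alone. The fatty acid oxidation score was 0.445 and 0.212 on combination replicates 2 and 3, whose red cell scores were -1.05 and -0.88, and -0.157 and -0.138 on replicates 1 and 4, whose red cell scores were 0.51 and 0.64. Without combination replicate 2 that list had adjusted p = 0.94, and other omissions ended the calls of immediate early genes (up to 0.221) and atrophy genes (up to 0.143). Ace had -0.71 (SE 0.29) and Vdr 0.31 (SE 0.21). The renin-angiotensin and vitamin D lists had medians of 0.09 and 0.00 (camera adjusted p = 0.876 and 0.989, and both at adjusted p = 0.993 with an estimated correlation). In 4.2% of genes the groups did not overlap, where chance gives 2.9%. Lsm5 did not pass in any of the 8 omissions of a single array. The count was 1 without combination replicate 2 or replicate 3, from a different gene, and 0 in the other 6.

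The combination against enalapril alone asked what paricalcitol added. No gene passed in limma (smallest adjusted p = 0.252). Only 754 had an unadjusted p under 0.05, where chance gives 711. All 20 immediate early genes were lower in the combination (median -0.57), with Nr4a1 at -1.05 (SE 0.38, n = 4 and 3), Egr1 at -1.57 (SE 0.70) and Junb at -0.70 (SE 0.31), at camera adjusted p = 3.06e-07 and adjusted p = 0.765 with an estimated correlation. Without enalapril replicate 2 the first of these was 0.0902. Collagen genes were lower in 30 of 37 members (median -0.22; adjusted p = 0.0017 and adjusted p = 0.843 with an estimated correlation), with Fmod, fibromodulin, at -0.42 (SE 0.13). Inflammation genes were lower in 22 of 30 (median -0.26; adjusted p = 0.0123 and adjusted p = 0.798 with an estimated correlation), with Il1b at -0.65 (SE 0.30). T cell markers were lower in 10 of 11 members (median -0.21; adjusted p = 0.0275 and adjusted p = 0.765 with an estimated correlation). Fatty acid oxidation genes were higher in 25 of 30 (median 0.11, or -0.01 in the deposited values without equalisation, where the median of all genes was -0.11; adjusted p = 0.0168 and adjusted p = 0.973 with an estimated correlation), with Slc25a20, the mitochondrial carnitine carrier, at 0.37 (SE 0.13). In these 5 lists 0 members passed adjusted over the list alone. The fatty acid oxidation score was high on combination replicates 2 and 3 alone, as given above, and without replicate 2 the list had adjusted p = 0.882. On the same replicates 2 and 3 the collagen scores were -0.747 and -0.395 and the inflammation scores -0.447 and -0.24, and on replicates 1 and 4 they were -0.104 and 0.189 for collagen and 0.03 and 0.011 for inflammation. Single omissions also ended the calls of collagen (up to 0.144), inflammation (0.0823) and T cell genes (0.193). Myh6 had 1.43 (SE 0.52). In 4.9% of genes the groups did not overlap, where chance gives 5.7%. With an array left out, 2 genes passed without enalapril replicate 2 or combination replicate 2, and 1 without enalapril replicate 3.

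The combination against paricalcitol alone asked what enalapril added. No gene passed in limma (smallest adjusted p = 0.174). At an unadjusted p under 0.05 the count was 1286, where chance gives 711. Smooth muscle and pericyte markers were lower in the combination in 9 of 12 members (median -0.38), with Tagln at -0.74 (SE 0.24, n = 4 and 4) and Acta2 at -0.58 (SE 0.22), at camera adjusted p = 0.00418 and adjusted p = 0.687 with an estimated correlation. Collagen genes were lower in 31 of 37 members (median -0.22; adjusted p = 0.0041 and adjusted p = 0.759 with an estimated correlation), with Fn1, fibronectin, at -0.96 (SE 0.35). Inflammation genes were lower in 25 of 30 (median -0.29; adjusted p = 0.0041 and adjusted p = 0.687 with an estimated correlation), with Vcam1 at -0.62 (SE 0.20). Genes of the TCA cycle were higher in 15 of 18 members (median 0.08; adjusted p = 0.00564 and adjusted p = 0.759 with an estimated correlation), with Idh3a at 0.28 (SE 0.07). Hypoxia-inducible genes were lower in 13 of 17 (median -0.13; adjusted p = 0.0467 and adjusted p = 0.759 with an estimated correlation), with Bnip3 at -0.35 (SE 0.10). Adjusted over the list alone, 3 TCA cycle genes and 1 muscle marker passed, and 0 in the other 3 lists. The inflammation score was 0.776 on paricalcitol replicate 4 and -0.259 to 0.078 on the others of that group, and without that array the list had adjusted p = 0.333. Single omissions also ended the calls of collagen (up to 0.138), TCA cycle (0.328) and hypoxia-inducible genes (0.352). TCA cycle scores were 0.18 and 0.102 on combination replicates 2 and 3, with low red cell scores, and -0.051 and -0.016 on replicates 1 and 4. Smooth muscle and pericyte scores were -0.012 and -0.018 on the former and -0.203 and -0.254 on the latter. With the replicate number as a block, 1 gene passed: C5ar1, a receptor of complement, at -0.76 (adjusted p = 0.0019 against 0.174 without the block), named after its value was seen; with the block in these groups alone 0 genes passed. The block also brought matrix proteases (adjusted p = 0.0446 against 0.0611) and endothelial markers (adjusted p = 0.0465 against 0.0611), both lower, past the threshold in camera, and all lists had adjusted p = 0.629 with an estimated correlation and the block. Groups did not overlap in 3.4% of genes, where chance gives 2.9%.

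The interaction asked whether paricalcitol acted differently with enalapril than without it. No gene passed in limma (smallest adjusted p = 0.113). Of all genes 987 had an unadjusted p under 0.05, where chance gives 711. The count was 2 without enalapril replicate 2 and 1 without combination replicate 3. With the replicate number as a block 1 gene passed, and 2 with the block in these 4 groups alone. Inflammation genes had a negative difference in 28 of 30 members (median -0.60), with Vcam1 at -1.05 (SE 0.29; n = 4, 4, 3 and 4). Smooth muscle and pericyte markers did so in 10 of 12 (median -0.57), with Tagln at -0.94 (SE 0.36). Camera gave adjusted p = 0.00021 for the former and 0.000294 for the latter, and both had adjusted p = 0.401 with an estimated correlation. Collagen, unfolded protein response, immediate early, macrophage and T cell lists were also past the threshold at the preset correlation, with negative medians from -0.43 to -0.29, and had adjusted p from 0.401 to 0.915 with an estimated correlation. Single omissions ended each of these 5 calls (up to 0.402, for immediate early genes without enalapril replicate 2). Among the vitamin D genes Cdkn1a, a cell cycle inhibitor, had -0.87 (SE 0.23; adjusted p = 0.416), and Lss had 1.31 (SE 0.21; adjusted p = 0.113).

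**Figure D3:**
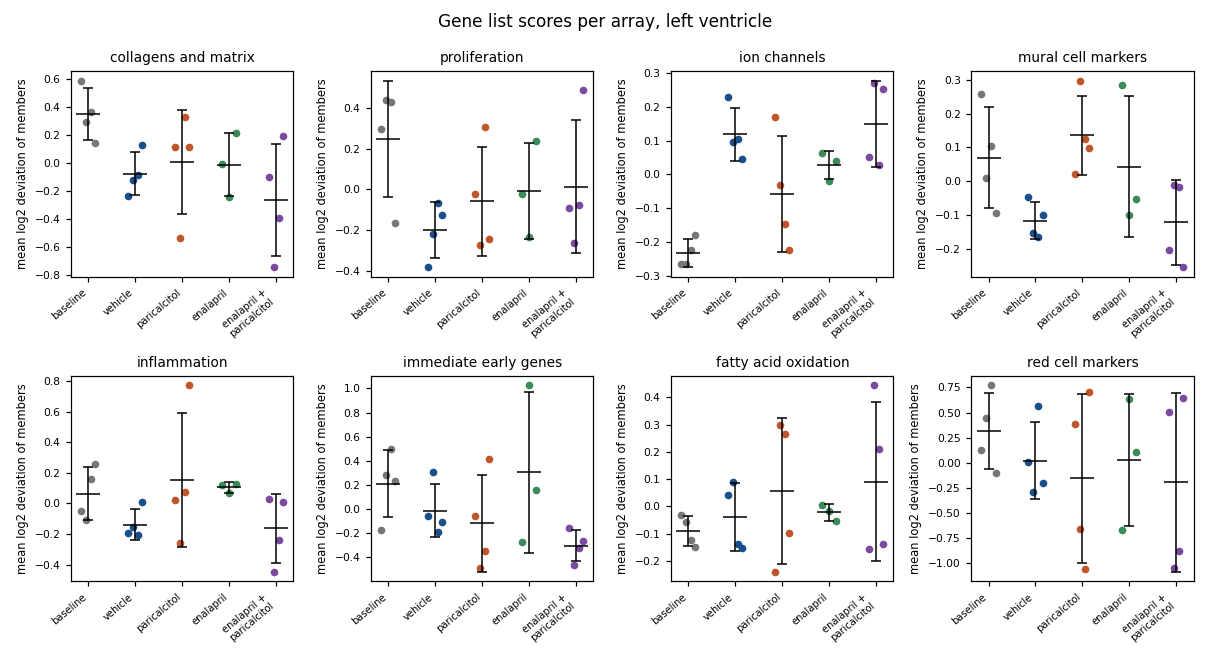
Mean log2 deviation of the members of 8 gene lists from their mean over all arrays, with each array as a point, the group mean as a bar and the SD as whiskers. Collagen scores had a group mean of 0.35 at baseline, -0.08 in vehicle and -0.26 in the combination.

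Each drug group against baseline asked how the treated hearts differed from hearts before treatment. In the combination 23 genes passed in limma (7 higher, 16 lower; 1470 at an unadjusted p under 0.05, where chance gives 711). Sparc, a collagen-binding matrix protein, fell by 0.66 (SE 0.08, n = 4 and 4; adjusted p = 0.00441), Hdgf, a growth factor, by 0.51 (SE 0.07), Igf2 by 0.82 (SE 0.14), Itga1, a collagen receptor subunit, by 0.50 (SE 0.09), and Cacna2d1, a calcium channel subunit, by 0.78 (SE 0.13). The log2 difference of Igf2 ran from -1.001 to -0.231 over the alternatives and omissions. Perm1, a regulator of mitochondrial genes in muscle, rose by 0.74 (SE 0.13), and Prkag1, a subunit of AMP-activated kinase, by 0.37 (SE 0.05). Sparc, Hdgf, Prkag1 and Cpsf7, an RNA processing factor that fell by 0.45 (SE 0.05), kept their calls in all 8 omissions of a single array, and in 11, 11, 11 and 10 of 14 other alternatives (highest adjusted p = 0.443, 0.447, 0.598 and 0.637). The count was 1 with only the compared groups in the model, and 2 in the deposited values or with probe sets averaged. Under omissions it lay between 5 without combination replicate 2 and 20 without combination replicate 3. It was 9 without combination replicate 4, and 11, 10 and 13 without baseline replicates 1, 2 and 3. Collagen genes were lower in 36 of 37 members (median -0.56; adjusted p = 8.39e-12 and adjusted p = 0.212 with an estimated correlation), and Sparc alone of them passed adjusted over the list. Fatty acid oxidation genes were higher in 27 of 30 (median 0.16; 1 passed adjusted over the list alone; adjusted p = 5.19e-05 and adjusted p = 0.717 with an estimated correlation), with Slc25a20 at 0.50 (SE 0.12). Matrix proteases were lower in 16 of 21 members (median -0.20; 3 passed adjusted over the list alone; adjusted p = 0.00819 and adjusted p = 0.212 with an estimated correlation), with Mmp14 at -0.81 (SE 0.16). Ion channel, TCA cycle, inflammation, cell cycle, immediate early and mural cell lists also passed at the preset correlation, and had adjusted p from 0.212 to 0.717 with an estimated correlation. The collagen scores were -0.747 and -0.395 on combination replicates 2 and 3, with low red cell scores, and -0.104 and 0.189 on replicates 1 and 4, against 0.143 to 0.589 at baseline. The fatty acid oxidation score was high on combination replicates 2 and 3, and on replicates 1 and 4 it lay at -0.157 and -0.138, against -0.149 to -0.031 at baseline. Adjusted over the list alone, 1 ion channel gene and 1 TCA cycle gene passed, and 0 in the other 4. Single omissions ended all list calls but those of collagen and immediate early genes. The TCA cycle median was 0.10, and -0.03 in the deposited values, or 0.11 above the median of all genes there. Groups did not overlap in 5.6% of genes, where chance gives 2.9%.

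Paricalcitol against baseline had 4 genes past the threshold (1 higher, 3 lower; 1103 at an unadjusted p under 0.05, where chance gives 711). Amph, amphiphysin, rose by 0.82 (SE 0.13, n = 4 and 4), Exoc8, a subunit of the exocyst, fell from 5.90 ± 0.19 (SD, n = 4) to 4.43 ± 0.35 (SD, n = 4), near the floor of 4, so no fold is given, Ywhab, a 14-3-3 protein, fell by 0.20 (SE 0.03), and Nmu lay at the floor on all paricalcitol arrays. The call of Ywhab was kept in 3 of 14 alternatives and 0 of 8 omissions of an array, that of Amph in 8 of 13 and 2 of 8, and that of Exoc8 in 9 of 13 and 2 of 8. Interferon-stimulated genes were lower in 18 of 20 members (median -0.35; 0 passed adjusted over the list alone; adjusted p = 0.000146 and adjusted p = 0.931 with an estimated correlation), with Isg15 at -0.78 (SE 0.28) and Irf7 at -0.61 (SE 0.22). Fatty acid oxidation genes had a median of 0.13 (-0.01 in the deposited values, or 0.16 above the median of all genes there; camera adjusted p = 0.000287) and cell cycle genes of -0.30 (adjusted p = 0.00268). Both had adjusted p = 0.931 with an estimated correlation, and 0 members passed adjusted over either list alone. Without paricalcitol replicate 2 they had adjusted p = 0.258 and 0.206. The fatty acid oxidation score was 0.298 and 0.266 on paricalcitol replicates 2 and 3, with red cell scores of -0.66 and -1.06, and -0.24 and -0.098 on replicates 1 and 4, with red cell scores of 0.39 and 0.70. In 3.7% of genes the groups did not overlap, where chance gives 2.9%. Enalapril against baseline had 2 genes past the threshold, both lower (1146 at an unadjusted p under 0.05): Thbd, thrombomodulin, fell by 0.55 (SE 0.08, n = 3 and 4), and Nmu lay at the floor on all enalapril arrays. Thbd kept its call in 7 of 14 alternatives and 1 of 7 omissions. TCA cycle genes had a median of 0.08 (camera adjusted p = 0.00921 and adjusted p = 0.833 with an estimated correlation) and T cell markers of 0.45 (adjusted p = 0.00921 and adjusted p = 0.574 with an estimated correlation). In both, 0 members passed adjusted over the list alone, and single omissions ended the calls (up to 0.128 and 0.0737). In 8.9% of genes the groups did not overlap, where chance gives 5.7%. Collagen genes were lower than at baseline in 32 of 37 members with paricalcitol (median -0.31; adjusted p = 0.000221 and adjusted p = 0.931 with an estimated correlation) and in 30 of 37 with enalapril (median -0.38; adjusted p = 0.000965 and adjusted p = 0.815 with an estimated correlation). Adjusted over the list alone, 1 collagen gene passed in each, and without paricalcitol replicate 2 the former list had adjusted p = 0.206. Nmu was lower in all 4 comparisons with baseline, which share the baseline arrays. Thbd also passed as lower in vehicle against baseline, and Ywhab in the combination against baseline, so neither fall was particular to 1 drug group. For paricalcitol the count was 0 without baseline replicate 3 or paricalcitol replicates 1, 2 or 3, 1 without baseline replicate 2 or replicate 4, and 8 without paricalcitol replicate 4. For enalapril it was 0 without baseline replicate 1 or enalapril replicate 3, 1 without baseline replicate 2, baseline replicate 4 or enalapril replicate 1, and 5 without baseline replicate 3.

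Whether the drugs turned back the change from baseline to vehicle was examined with the vehicle arrays divided into pairs, 1 pair used to choose 200 genes and the other to compare. The 200 were those with the smallest p against baseline. Only 0 to 13 genes passed the threshold in a split, so most of the 200 had not passed. Signed by the direction of the vehicle change, the median log2 difference of those genes was -0.15 with paricalcitol (6 splits, -0.18 to -0.12), -0.06 with enalapril (-0.09 to -0.02) and -0.07 with the combination (-0.11 to -0.05), and the sign was negative in 6 of 6 splits for each. In the deposited values it was -0.143 with paricalcitol and -0.197 with enalapril, so the order of the drugs depended on the processing. The splits share arrays, and no test was made. Both pairs belong to the vehicle cohort, so an offset of that cohort would also give negative values in every drug group. Across genes, which are not independent replicates, the effects of paricalcitol and of enalapril correlated at 0.459 with the vehicle arrays in common, where simulated unchanged groups gave 0.466, and at 0.091 (0.021 to 0.123 over 6 splits) with separate vehicle arrays.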

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

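The tests of other splits, the fibroblast test and the omission of several arrays were chosen after the results were seen. The other tests were set down before their values were known, but the inflammation pattern was set aside for a time and taken up again after its values had been seen.

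The genes named in the text showed 1 rat apart from the others of its group in 15 of 293 sets of values of a group, and the list scores in 2 of 92. Chance gives about 1 in 20. Cd93 was 8.14 on baseline replicate 1 and 7.57 to 7.67 on the others. Myh6 was 11.57 on baseline replicate 4, against 13.11 to 13.34. Nmu was 4.85 and Far1 4.47 on combination replicate 1, with the others at the floor of 4, and Nmu was 4.01 on vehicle replicate 1. Insig1 was 8.84 and Rgs5 9.64 on combination replicate 4, against at least 8.99 and 10.01. Mcm4 was 6.54 on combination replicate 2 (6.98 to 7.03), and Amph 7.11 on combination replicate 3 (6.79 to 6.82). Among vehicle arrays, Atp6v0e2 was 8.70 on replicate 1 (9.01 to 9.05), Myh7 14.05 on replicate 3 (14.12 to 14.14) and Nppa 14.39 on replicate 1 (14.42). Among paricalcitol arrays, Thbd was 9.70 (9.54 to 9.56) and Trim54 11.42 (11.69 to 11.72) on replicate 3, and Itga1 8.87 (8.65 to 8.68) on replicate 1. The T cell score was -0.29 on combination replicate 1 and 0.05 to 0.11 on the others, and the endothelial score -0.01 on paricalcitol replicate 1 and 0.12 to 0.13 on the others.

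The effect of paricalcitol differed with and without enalapril in 7 lists at the preset correlation of camera, by a mean log2 difference of -0.56 for inflammation, -0.50 for immediate early genes and -0.42 for smooth muscle and pericyte markers. It was -0.35 for macrophage markers, -0.34 for collagens, -0.33 for T cell markers and -0.26 for the unfolded protein response. None of the 7 passed with an estimated correlation (adjusted p from 0.401 to 0.915). Probe sets that name no single gene, which no comparison used, passed in 8 comparisons. These were 19 in the combination against baseline, 5 in the combination against vehicle, 3 in enalapril against baseline, 2 in the combination against paricalcitol, and 1 each in vehicle against baseline, enalapril against vehicle, the combination against enalapril and the interaction.

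Arrays of both groups given paricalcitol differed more from each other than the other arrays did: over 8710 genes the median SD within groups was 0.213 with paricalcitol (8 arrays) and 0.157 without (11 arrays), a ratio of 1.36, with an exact permutation p = 2.65e-05 on squared deviations, which are not independent within a group. The permutation moved single arrays, although the drug was given to whole groups. Deviations of equal-numbered arrays also correlated at 0.28 to 0.50 between both groups. That p therefore overstates the evidence for a link with paricalcitol. Array brightness and normalization are argued against, since the ratio was at least 1.34 under 3 other normalizations. A few deviating arrays stay open: the ratio was at least 1.29 with any 1 of the 8 left out, but 0.89, the lowest of all omissions of up to 4 arrays, without replicates 1 and 4 of both groups. Red cell RNA is a candidate explanation too, with a ratio of 1.07 once the red cell marker score was taken out of each gene, and a state of the heart that varies with that score would give the same value. The biological explanation, a response to paricalcitol that differs between rats, stays open and was not tested beyond this.

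Collagen and matrix genes were lower in vehicle than in baseline hearts, with a difference in list score of -0.43. The difference was -0.37 or further from 0 in 3 other normalizations. The list median relative to all genes was -0.43 in the main processing and -0.44 in each of these. Median centring shifts all genes of an array alike, so its relative median only repeats that of the deposited values. Neither measure of size was the criterion set beforehand. These sizes argue against normalization as the source of the list difference. By the criterion set beforehand normalization was not excluded, as the groups overlapped: the highest vehicle score exceeded the lowest baseline score by up to 0.08 in these normalizations. That decides little, as this margin was only -0.01 in the main processing. Fewer fibroblasts may account for the difference: fibroblast markers were lower as well (-0.20), and the difference between both scores had an exact permutation p = 0.143, which does not show that they moved alike. Age, vehicle injections and cohort, which differ between these groups, stay open and untested.

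The effect of paricalcitol on inflammation genes differed with enalapril, by -0.56 in list score (exact permutation p = 0.0298, not adjusted for 38 lists). A single array remains a possible explanation: without paricalcitol replicate 4, the highest of its group, the difference was -0.35, between the bounds set for either answer. More leukocytes in some hearts are a candidate explanation too, since the macrophage score differed by -0.35 and the inflammation score minus it had an exact permutation p = 0.423. That p does not show that both scores moved alike. Macrophage scores varied widely between arrays, with an SD of 0.46 with paricalcitol and 0.44 in the combination. The interaction of both drugs, the biological explanation of the design, stays open.

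Other splits of the same arrays into groups of the same sizes show where chance can be excluded at a share under 0.05, before any adjustment. It can be so for the genes of vehicle against baseline (12 genes; 1 of 35 splits gave as many, highest other 2), paricalcitol against vehicle (2; 1 of 35, highest other 1, a margin of 1 gene), paricalcitol against baseline (4; 1 of 35, highest other 1) and the combination against baseline (23; 1 of 35, highest other 7). A share of 1 of 35 is the smallest possible, and adjusted for the 20 counts tested it would exclude chance in none of them. It cannot be for the combination against vehicle (1; 4 of 35, highest other 1) and enalapril against baseline (2; 3 of 35, highest other 4). Where no gene passed every split has as many, so the splits say nothing on chance: 35 of 35 in enalapril against vehicle (highest other 1), the combination against enalapril (highest other 6) and the combination against paricalcitol (highest other 1703), and 100 of 100 in the interaction (highest other 3). The split with 1703 genes set replicates 1 and 4 of both groups against replicates 2 and 3 of both, which points to a structure of the samples and divides them as the red cell score does. For lists at the preset correlation chance cannot be excluded anywhere. The splits did not keep arrays of equal number together, so in the combination against paricalcitol, where such arrays resembled each other, they say less. As many were called by 13 of 35 splits in vehicle against baseline (4 lists, highest other 7), 31 in paricalcitol against vehicle (2, 11), 6 in enalapril against vehicle (5, 8), 20 in the combination against vehicle (3, 12), 21 in the combination against enalapril (5, 13). They were called by 23 in the combination against paricalcitol (5, 14), 28 in paricalcitol against baseline (4, 13), 24 in enalapril against baseline (3, 9) and 9 in the combination against baseline (9, 11), and by 27 of 100 for the interaction (7, 11).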

How the results depend on the processing

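The choice of cyclic loess, of the block within the compared groups, of the red cell covariate, of array-level list tests and of the deposited values and the block for lists was made after seeing the data. Among named genes, 9756 values under the alternatives kept their direction and their side of the threshold, 376 lost a call and 48 gained one. In 244 the direction differed, with no call in either fit. Most of the 9756 were values of genes without a call in the main fit, which had none to lose. They do not show that calls were stable, and the 376 weigh against the values of called genes alone. Among lists past the threshold, 428 values were unchanged in this sense, 258 lost the call and 1 turned. Gene counts past the threshold moved by over 1.5 times as follows, with V vehicle, B baseline, P paricalcitol, E enalapril and C the combination. Deposited values without equalisation: V-B 3 (0 higher), P-V 1 (higher, where both calls were lower), C-V 0, interaction 1, E-B 0, C-B 2 (0 higher), with the median of all genes at -0.20 in V-B, 0.17 in E-V, -0.11 in C-E, -0.14 in the interaction, -0.17 in P-B and -0.14 in C-B. Median centring: V-B 22 (14 higher), P-V 71 (64 lower), C-V 0, E-B 0, and, within that range, C-B 17 (10 higher, 7 lower, against 7 and 16). Cyclic loess: P-V 1, C-V 0, and, within that range, V-B 17 (6 higher, 11 lower, against 3 and 9) and C-B 16 (7 higher, 9 lower). Dimmer genes left out: P-V 9, C-V 0, P-B 0, E-B 4, C-B 43. No trend: P-V 1, E-B 4, C-B 14. Array weights: V-B 160, among them the 12 found without weights, P-B 2, E-B 19, C-B 70. Only the compared groups: V-B 45, P-V 1, C-V 2, P-B 0, E-B 0, C-B 1. Probe sets averaged: V-B 7, C-P 1, E-B 0, C-B 2. Probe sets tested singly: P-V 4, C-V 2, P-B 7, E-B 8, C-B 45. Replicate block: V-B 19, P-V 14, C-V 2, C-P 1, interaction 1, P-B 7, E-B 0; in the compared groups alone it left 0 in V-B, P-V, C-V, P-B, E-B and C-B and gave 2 in the interaction. In C-P, where arrays of equal number resembled each other, the block gave 7 lists against 5, and in the compared groups alone 0 genes. Replicates 1 and 4 of both groups differed from replicates 2 and 3, which would give that resemblance without any pairing. Pseudocount 1: E-V 1, C-E 1, interaction 1, E-B 6; pseudocount 64: E-B 0. Red cell score as a covariate: V-B 43, P-V 9, C-V 2, P-B 0. With 1 array left out the counts ran from 0 to 5 in V-B, 0 to 10 in P-V, 0 to 2 in E-V, 0 to 1 in C-V, 0 to 2 in C-E, 0 to 0 in C-P, 0 to 2 in the interaction, 0 to 8 in P-B, 0 to 5 in E-B and 5 to 20 in C-B. List counts fell to 0 in all 10 comparisons with an estimated correlation, with fry and with exact array-level tests. For the last this says little between a pair of groups, where the smallest possible exact permutation p was 0.0286 before adjustment over 38 lists. With the dimmer genes left out they were V-B 2, P-V 1, E-V 1, E-B 1 and C-B 5, and with deposited values P-V 4, E-V 2, C-V 7, C-E 3 and E-B 7. Without the dimmer genes too few members of the cell cycle and T cell lists were kept, so these were not tested. Part of the fall in V-B and C-B (cell cycle) and in E-V and E-B (T cells) is therefore not a lost call. With 1 array left out the list counts ran from 3 to 10 in V-B, 1 to 6 in P-V, 2 to 7 in E-V, 0 to 5 in C-V, 3 to 7 in C-E, 2 to 14 in C-P, 5 to 10 in the interaction, 1 to 6 in P-B, 3 to 5 in E-B and 5 to 13 in C-B. The immediate early list in E-V (list immediate_early: enalapril against vehicle) had p values signed by direction from -0.362 without enalapril replicate 2, where it turned (adjusted p = 0.692), to 0.0346 without vehicle replicate 4. The reversal of the vehicle change was -0.20 for paricalcitol without the dimmer genes and -0.117 with averaged probe sets, -0.197 for enalapril and -0.104 for the combination in deposited values, and -0.198 to -0.121, -0.094 to -0.028 and -0.107 to -0.052 with 1 array left out. The correlation of both drugs' effects was 0.186 without the dimmer genes, and 0.044 to 0.119 with 1 array left out. The cause was not tested. Signal over background limits the faint genes, with 16% to 18.2% of the values of an array below 0.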

Other observations

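The relation of Nppb to the red cell score was noticed in all arrays first and then tested, so the tests of it here were chosen after seeing it.

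Nppb, the natriuretic peptide that heart muscle releases under stretch, was higher in hearts with more red cell RNA. Over the 11 arrays without paricalcitol, as deviations from group means, Pearson's r was 0.83 (exact permutation p = 0.000289, the smallest possible) and Spearman's rho 0.94 (exact permutation p = 0.000289). The adjusted p was 0.0113 for each over 39 relations computed in that family, and 1 of the 39 passed. In the 8 arrays with paricalcitol 3 of 39 passed by Pearson's r (Nppb, Nppa and the TGF-beta list, exact permutation tests, adjusted p = 0.0451 each). By Spearman's rho none passed there (exact permutation tests, lowest adjusted p = 0.0677). Deviations of equal-numbered arrays correlated at 0.28 to 0.50 between both groups, so the 8 arrays are not independent. The permutations did not allow for that. Over the 11 arrays without paricalcitol, r of Nppb was 0.77 without the 2 arrays farthest in the red cell score. With each array's median brightness taken out of both measures it was 0.87 in those 11. In the 8 arrays with paricalcitol the red cell score fell into separate clusters, with 0.39, 0.70, 0.51 and 0.64 on replicates 1 and 4 of both groups and -0.66, -1.06, -1.05 and -0.88 on replicates 2 and 3. For that reason no pooled correlation is given.

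The red cell markers differed in level. The log2 level of Hbb ran from 13.62 to 14.28 over the arrays and that of Hba-a3 from 11.88 to 13.12. Alas2, the enzyme of haem synthesis in red cell precursors, ran from 9.17 to 11.66 and Slc4a1 from 8.17 to 10.5. Ahsp ran from 6.56 to 9.78 and Epb42 from the floor of 4 to 6.56. Genes of MHC class II had a median of 0.40 in paricalcitol against vehicle (camera adjusted p = 0.179, and adjusted p = 0.845 with an estimated correlation). They had 0.40 in the combination against vehicle (adjusted p = 0.0999, and 0.993 with an estimated correlation), and passed in neither. The MHC class II scores were 0.3 and 0.753 on paricalcitol replicates 2 and 3, with low red cell scores, and -0.328 and -0.208 on replicates 1 and 4; in the combination they were 0.402 and 0.237, and -0.35 and 0.313.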
